A study of Gallus gallus with 24 samples.

How the data were processed

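RNA sequencing of chicken jejunum gave 24 libraries, 6 in each of 4 groups formed by the line (HAS or LAS) and by injection with sheep red blood cells. The deposited table holds 1 column per library in TPM for 15618 genes, 12132 with a symbol and 3486 listed by identifier only. The unit was read from the values, which are not whole, are never below 0 and sum to nearly the same total in each column; the authors scaled them over the genes listed. Per the submitters' notes the genome build was galGal6, and the aligner, the counting tool and the annotation release are not given. Read counts are not in the table, so the depth of the libraries is unknown and no interval from counting error can be computed.

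Genes with at least 0.5 TPM in at least 6 libraries were tested, which left 13279. A filter made for counts had been planned and could not be applied to TPM. Values were used as log2(TPM + 1). All 24 libraries were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group, empirical Bayes moderation with an intensity trend, robust settings and 20 residual degrees of freedom. The contrasts were HASN vs LASN, HASI vs LASI, HASI vs HASN, LASI vs LASN, the interaction of line and injection, and the average of both injection effects. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within a contrast, and a gene was called at an adjusted p below 0.05. Symbols and identifiers are those of the table.

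The genes named were set by a rule. It took the 8 called genes with the highest and the 8 with the lowest log2 fold change among those with a symbol and a mean of at least 1 TPM, and the 2 members of each gene list with the smallest adjusted p where called. It added BF1, BF2, BLB1, BLB2, JCHAIN and PIGR whatever their result, 2 genes without a symbol at each end, and, where fewer than 5 genes were called, the 5 with the smallest p. The genes the rule took are named with few left out, and those whose call ended under another setting are set apart in each comparison. CD74 was in the rule and is not in the table under that symbol. The groups, contrasts, test, naming rule, gene lists and most alternatives were fixed before the data were examined.

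Gene lists of cell type markers and pathways were tested with camera from limma at a preset correlation of 0.01, with an estimated correlation and the rotation test fry as alternatives. Of 26 lists, 24 had at least 5 tested members. Members called were counted over all genes and again with p-values adjusted over the list alone. Overlaps of called genes and the share of called genes by chromosome were tested with Fisher's exact test, the latter over 24 tests and with all tested genes as background.

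For each library the mitochondrially encoded share of TPM, the number of genes above 0 and the slope of log2(TPM + 1) on the log2 genomic span of genes were computed. Groups were compared in them by exact permutation tests over 16 comparisons, and correlations over libraries by 1e+05 permutations. No batch, date or bird sex is given in the labels. The 276 pairs of libraries had correlations of 0.797 to 0.988, and 0 pairs were identical.

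The other settings tried were median-ratio rescaling, no filter, a filter at 1 TPM, a pseudocount of 0.1, a log2 fold change of at least 1, only the groups compared, the replicate number as a block, 2 surrogate variables, the level of chromosome W genes as a covariate, and each library left out in turn. The surrogate variables came from an own implementation of the iteratively reweighted procedure. Over the libraries the first followed the span slope (absolute r = 0.979) and the second the level of chromosome W genes (absolute r = 0.957). Fits with the surrogate variables and with the slope are therefore not independent alternatives. The slope of each library as a covariate, which is computed from the values it then adjusts, and the joint omission of LASI replicates 4 and 6 were added after the data were seen. Fits within sets of libraries formed by their slope were tried and are not reported, since such sets are defined by a measured outcome. Alternatives that need counts were not run.

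The procedure was tested on simulated data with 6 libraries per group and 100 changed genes for each size of change. Of changes of 1 on the log2 scale 57.2% to 61.0% were recovered, and of changes of 2 between 90.6% and 92.6%, with 5.8 to 9.2 false calls on average when noise was independent between genes. With noise that kept the shared structure of the libraries, the false calls for HASI vs LASI were 3114 in 1 of 5 draws and at most 2 in each of the other 4. With the slope as a covariate those for LASI vs LASN were 363 in 1 draw and at most 20 in each of the other 4.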

Results

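Expression was measured by RNA sequencing in the jejunum, the middle part of the small intestine, of 24 chickens. The birds came from HAS and LAS, lines bred in opposite directions for a high or a low antibody response to sheep red blood cells (SRBC), an antigen. Birds injected with SRBC form the groups HASI and LASI, birds that were not injected form HASN and LASN, and each group holds 6 birds with 1 library each. The label of every sample gives 5 days post injection. Values are relative transcript abundances scaled to the same total in every library (TPM) for 15618 genes, of which 13279 were tested. The files keep no read counts, so the depth of each library is unknown and no counting interval can be given. The number of genes above 0 TPM averaged 14201 ± 430 (SD, n = 6) in HASN, 14349 ± 56.2 in HASI, 14359 ± 364 in LASN and 14403 ± 106 in LASI.

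Libraries differed in ways that go with injection. The 13 mitochondrially encoded genes took 17.5% ± 4.53 of all TPM in HASN and 27.8% ± 6.86 in HASI (exact two-sided permutation p = 0.00866). They took 15.0% ± 3.32 in LASN and 22.1% ± 4.05 in LASI (exact permutation p = 0.0108). Adjusted over the 16 comparisons of library measures, both of these exact p-values became 0.0577. Long genes were also less abundant relative to short genes in some libraries. The slope of log2(TPM + 1) on the log2 genomic span of genes was -0.12 ± 0.13 in HASN, -0.16 ± 0.05 in HASI, -0.05 ± 0.06 in LASN and -0.18 ± 0.07 in LASI. Within HASN the slope was -0.22, -0.28 and -0.24 in replicates 1 to 3 and 0.0041, -0.02 and 0.01 in replicates 4 to 6. That split was noticed after the values were seen. The LAS groups differed in the slope by an exact permutation test (p = 0.00866, adjusted 0.0577), and the HAS groups did not pass that test (exact p = 0.485). The first principal component held 67.3% of the variance and followed this slope over the 24 libraries (Pearson r = -0.979, Spearman rho = -0.962, each with a permutation p of 1e-05, the smallest the permutations can give, or 2e-05 for rho after adjustment over 2 relations). Without the 2 libraries farthest from the median slope, r was -0.973. The component also followed the mitochondrially encoded share (Pearson r = 0.791, permutation p = 1e-05, Spearman rho = 0.803, permutation p = 4e-05). Without the 2 libraries farthest from the median share, r was 0.830. Slope, share and component are all computed from the same values, so these p-values do not relate independent measures.

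**Figure D1:**
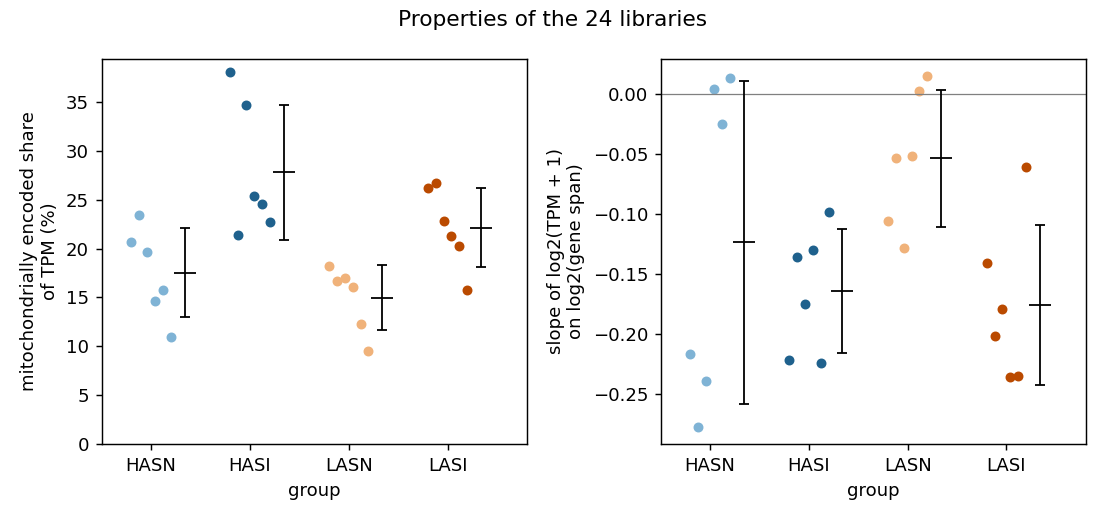
Mitochondrially encoded share of TPM (left, %) and slope of log2(TPM + 1) on log2 gene span (right) for each of the 24 libraries (points), with the mean and SD of each group of 6 in black. The share averaged 17.5% in HASN, 27.8% in HASI, 15.0% in LASN and 22.1% in LASI.

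Comparing HASN with LASN asks which genes differ by selection line without the antigen. Large differences lay at neighbouring genes on chromosome 24 and in the major histocompatibility complex (MHC) on chromosome 16. ST3GAL4 (ENSGALG00000029747, chromosome 24, 473593 to 483311), a sialyltransferase, was at 6.48 ± 1.63 TPM in HASN and 481 ± 90.6 in LASN (SD, n = 6), a log2 fold change of -6.02 (SE 0.20, adjusted p = 1.03e-15). KIRREL3 (ENSGALG00000029197, chromosome 24, 484288 to 720481), which encodes a cell adhesion protein, was at 0.533 ± 0.273 TPM against 73.7 ± 14.2, a log2 fold change of -5.60 (SE 0.24, adjusted p = 5.03e-14). In each of these genes all 6 HASN libraries lay below every LASN library.

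Of the 21 measured genes of the MHC and antigen presentation list, 1 was higher and 4 were lower in HASN (2 and 6 when adjusted over the list alone). BLB1 (ENSGALG00000000141, chromosome 16, 2565094 to 2566926), an MHC class II beta chain, was at 264 ± 45.9 TPM against 1722 ± 224 in LASN, a log2 fold change of -2.71 (adjusted p = 7.73e-11). BG8 (ENSGALG00000049461, chromosome 16, 2283023 to 2395890), a member of the chicken BG family, was at 77.3 ± 20.2 TPM against 497 ± 61.9 (log2 fold change -2.70, adjusted p = 4.97e-12). The class I genes went in opposite directions: BF1 (ENSGALG00000033932, 2565405 to 2595262) was lower in HASN by a log2 fold change of -1.43 (adjusted p = 2.0e-06) and BF2 (ENSGALG00000041380, 2606528 to 2609057) was higher by 0.96 (adjusted p = 0.000632). BLB2, the other class II beta gene, had a log2 fold change of 0.58 that did not pass (adjusted p = 0.138). The gene models of BF1, BLB1 and BLB2 overlap on the map, as do those of BG8 and several unnamed genes, and the BF genes and the BLB genes are close relatives in sequence, so the split of reads between them is uncertain. For the list as a whole, the median log2 fold change was 0.04, the mean was -0.29, and camera, which compares a list with all other genes, gave an adjusted p of 0.659. On chromosome 16, 13 of 84 tested genes were called, an odds ratio of 16.7 (95% interval 8.29 to 31.3, Fisher's exact test, p = 8.98e-11 adjusted over 24 tests).

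Other genes lower in HASN were MGAT5B, a glycosyltransferase (log2 fold change -2.63), the chloride channel gene CLCN1 (-2.47), RFLNA (-2.36) and TP53I3 (-2.17, SE 0.18, adjusted p = 2.27e-08). Higher in HASN were the Wnt inhibitor gene WIF1 (log2 fold change 1.57), ABHD3 (1.44), PCSK4 (1.39), the kinase gene VRK2 (1.34) and the DNA repair gene NTHL1 (1.19, adjusted p = 6.69e-05). The call of WIF1 ended when only HASN and LASN were fitted. The gene ENSGALG00000052196 on chromosome 23, which has no symbol in the file, was at 111 ± 16.8 TPM against 9.36 ± 2.24. Of 28 enteroendocrine genes, 0 were higher and 1, the motilin gene MLN, was lower (0 and 5 adjusted over the list alone). MLN was at 14.7 ± 7.27 TPM against 35.5 ± 12.5, and its call ended after rescaling, with only the groups compared, and without HASN replicate 3 (adjusted p = 0.0582) or LASN replicate 1 (0.0503), within a range of 0.00293 to 0.177 over its alternatives. JCHAIN, the joining chain of secreted antibodies, was at 832 ± 288 TPM in HASN and 1894 ± 627 in LASN and did not pass (log2 fold change -1.17, adjusted p = 0.0535). PIGR, which carries antibodies across the epithelium, had a log2 fold change of 0.42 (adjusted p = 0.458).

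The naming rule took 25 called genes, of which 17 kept their call in every refit that used no fold threshold. Among these were also the genes without a symbol ENSGALG00000049448 (log2 fold change -3.85) and ENSGALG00000050131 (-2.49), whose models overlap that of BG8. The other 8 lost their call when only HASN and LASN were fitted. Besides WIF1 and MLN they were TCF7, a transcription factor gene of T cells (-1.42), the chemokine genes CXCL14 (-0.71) and CCL4_1 (1.33), ASS1, an enzyme gene of arginine synthesis (1.23), LAPTM4B (1.25) and ENSGALG00000033498 (4.32). TCF7 also lost it without HASN replicate 1, 2 or 3 or LASN replicate 5 (adjusted p up to 0.0569, range over its alternatives 0.000198 to 0.148). ASS1 did so without HASN replicate 4 or LASN replicate 1, 2 or 3 (up to 0.0774, range 0.00248 to 0.169). CXCL14 did so without any library but HASN replicate 5 (up to 0.129, range 0.0045 to 0.284). LAPTM4B did so without any HASN library or LASN replicate 2, 3 or 5 (up to 0.13, range 0.00761 to 0.232). LAPTM4B and CXCL14 also lost it with no filter, with the filter at 1 TPM and with the pseudocount of 0.1. The replicate block and the W level as a covariate ended it for LAPTM4B, the slope as a covariate for CXCL14, and rescaling for CXCL14 and CCL4_1. CCL4_1 lost it without HASN replicates 1 to 4 or any LASN library but replicate 2 (up to 0.104, range 0.00266 to 0.129). ENSGALG00000033498 did so without HASN replicate 1, 4, 5 or 6 or LASN replicate 1, 2, 4 or 5 (up to 0.0592, range 0.000176 to 0.0744).

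In all, limma called 156 genes between HASN and LASN, 44 higher and 112 lower in HASN. Camera called 5 of 24 lists, each as higher in HASN than other genes, among them the ribosomal protein genes (adjusted p = 2.63e-16, with 0 of 76 members called), and 0 of the 5 kept the call (adjusted p = 0.916 with an estimated correlation). The median log2 fold change of all tested genes was -0.19, and median-ratio rescaling, which moved it to 0.0049, called 77 higher and 88 lower. The count was 282 with the span slope as a covariate, 435 with 2 surrogate variables and 67 when only these groups were fitted. The last fit took each gene's spread from these groups alone, and the main fit from all 4 groups. Whether the uneven span slopes within HASN lowered that count was not tested.

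**Figure D2:**
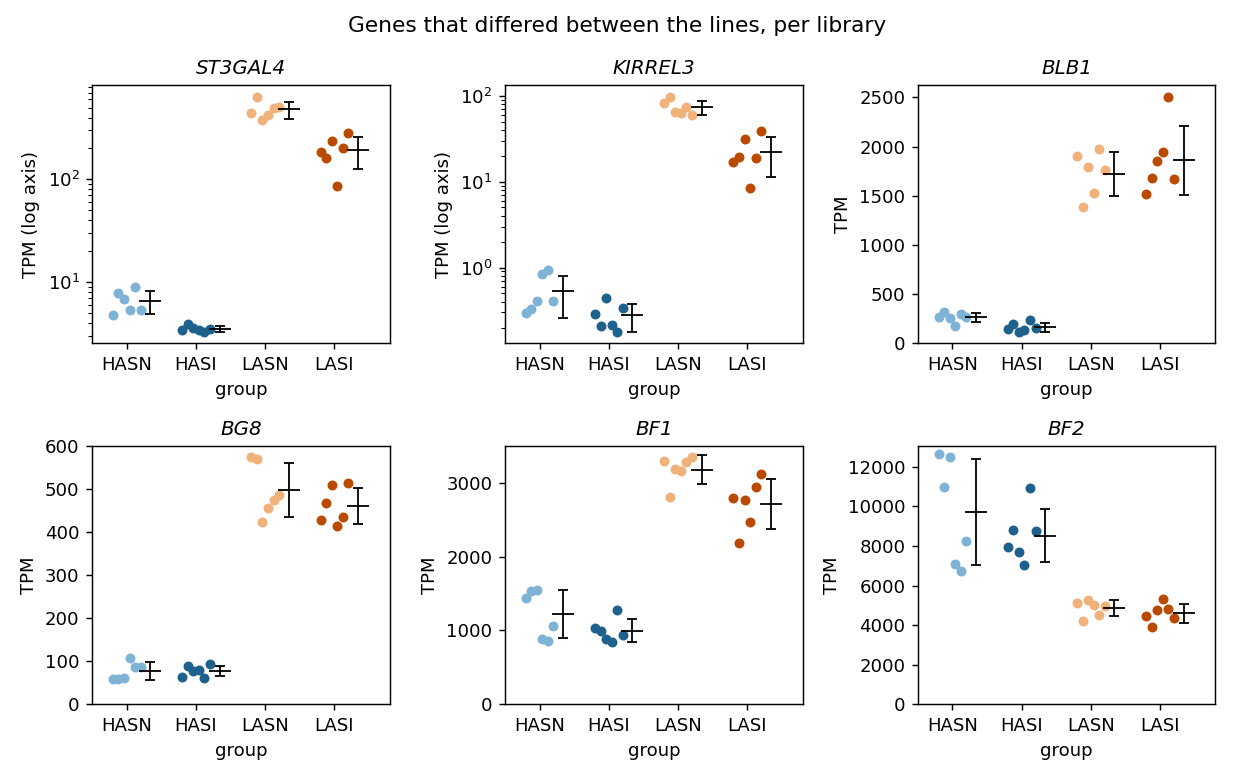
TPM per library (points) of ST3GAL4 and KIRREL3 (log axes) and of BLB1, BG8, BF1 and BF2 (linear axes) in the 4 groups, with the mean and SD of 6 libraries in black. All 6 genes separated the lines without overlap in uninjected and in injected birds, BF2 higher in HAS and the others lower, and BF2 lost its call in injected birds after median-ratio rescaling.

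Comparing HASI with LASI asks the same of birds given the antigen. Its groups hold other libraries than the comparison without it, but the spread of each gene was estimated from all 24 libraries. ST3GAL4 was again lower in HAS, at 3.51 ± 0.228 TPM in HASI and 193 ± 67.7 in LASI (SD, n = 6), a log2 fold change of -5.34 (SE 0.20, adjusted p = 1.52e-14). KIRREL3 had a log2 fold change of -4.05 (SE 0.24, adjusted p = 3.79e-11). BLB1 was at 166 ± 46.7 TPM against 1859 ± 351, a log2 fold change of -3.50 (SE 0.16, adjusted p = 4.85e-13). BG8 was lower by -2.57 and BF1 by -1.45, while BF2 was higher by 0.88 (adjusted p = 0.00244), a call that ended after rescaling although its log2 fold change was then 0.97.

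The MHC and antigen presentation list had 1 higher and 5 lower members of 21 in HASI, the same adjusted over the list alone and with the slope as a covariate, and 0 and 4 after rescaling. Camera called 8 of 24 lists, 3 higher and 5 lower, and of these it was the one, lower at an adjusted p of 5.2e-09, whose call held (adjusted p = 0.0164 with an estimated correlation). On chromosome 16, 13 of 84 genes were called (odds ratio 40.6, 95% interval 19.6 to 79.4, Fisher's exact test, adjusted p = 4.15e-15). The enteroendocrine list had 0 higher and 3 lower members of 28 (0 and 10 adjusted over the list alone, 0 and 1 after rescaling, 0 and 5 with the slope as a covariate), namely MLN (log2 fold change -1.34), the neurotensin gene NTS (-0.89) and PAX6 (-0.63, chosen after its values were seen). Camera called that list lower at an adjusted p of 4.27e-06, which was lost (adjusted p = 0.0927 with an estimated correlation). The call of MLN ended after rescaling, without LASI replicates 4 and 6 together, and without HASI replicate 2 (adjusted p = 0.0513), HASI replicate 3 (0.0634), HASI replicate 6 (0.0554) or LASI replicate 2 (0.0625), within a range of 0.00452 to 0.119 over its alternatives. That of NTS ended with only the groups compared, without LASI replicates 4 and 6 together, and without HASI replicate 1 (adjusted p = 0.0598), HASI replicate 3 (0.0632), HASI replicate 5 (0.0533) or LASI replicate 2 (0.0625), within a range of 0.00084 to 0.107. The 31 smooth muscle and stroma genes had a median log2 fold change of -0.49 with 0 members called (camera adjusted p = 6.55e-06, and adjusted p = 0.93 with an estimated correlation).

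CLDN1, a tight junction claudin gene, was lower in HASI at 2.42 ± 0.699 TPM against 6.45 ± 1.34 (log2 fold change -1.13, adjusted p = 0.00303). CFC1 (log2 fold change -1.83), BPIFB3 (-1.73), TP53I3 (-1.71) and ANKRD33 (-1.62) were also lower, and ABHD3 (1.72) and VRK2 (1.21) were higher. ENSGALG00000052196 was higher at 98.6 ± 9.46 TPM against 9.84 ± 1.45. JCHAIN (log2 fold change -0.43, adjusted p = 0.926), BLB2 (0.03) and PIGR (0.16) did not pass. The naming rule took 25 called genes here, of which 14 kept their call in every refit that used no fold threshold, ENSGALG00000049448 (log2 fold change -3.25) among them. Besides MLN, NTS, BF2 and NTHL1, those that lost it were the histone genes H2A-VII_6 (1.27) and HIST1H103 (1.76), the elastase gene CELA1 (0.61), GGACT (0.82), PLCD4 (0.93), ENSGALG00000036831 (-2.29) and ENSGALG00000051027 (5.60). Without LASI replicates 4 and 6 together all of them but BF2 and ENSGALG00000036831 lost it, and of the 7 last named H2A-VII_6, HIST1H103 and PLCD4 lost it after rescaling and GGACT, PLCD4 and ENSGALG00000036831 with only HASI and LASI fitted. CELA1 also lost it without HASI replicate 1, 3 or 5 or LASI replicate 5 (adjusted p up to 0.0692, range over its alternatives 0.00958 to 0.0858). HIST1H103 did so without HASI replicate 1, 3 or 5 or LASI replicate 2, 3 or 6 (up to 0.085, range 4.21e-05 to 0.149). ENSGALG00000036831 did so without HASI replicate 1, 3 or 5 or LASI replicate 3 or 5 (up to 0.0723, range 0.00408 to 0.0723). GGACT did so without any library but HASI replicate 4 (up to 0.147, range 0.00955 to 0.225), and PLCD4 without any but HASI replicates 2 and 6 (up to 0.135, range 0.00802 to 0.196). Both also lost it with no filter, and PLCD4 with the filter at 1 TPM and with the W level as a covariate.

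In all 72 genes were called, 21 higher and 51 lower, or 32 and 48 after rescaling. Leaving out HASI replicate 1 gave 47 calls, HASI replicate 3 gave 46 and LASI replicate 2 gave 45, and without LASI replicates 4 and 6 together there were 40. The span slope as a covariate gave 288 and 2 surrogate variables gave 406.

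The line differences of uninjected and injected birds overlapped. Their libraries were separate, but the same estimate of each gene's spread served both comparisons. The chance numbers and the p-value given for the overlap thus assume more independence than there is. Between the 156 and the 72 called genes, 44 were shared with the same direction and 0 with opposite directions. The shared genes were 12 higher in HAS, where 0.0696 would be shared by chance, and 32 lower, where 0.43 would be (Fisher's exact test for the overlap, p = 9.26e-69 across genes, which are not independent replicates). They include ST3GAL4, KIRREL3 and, chosen after their values were seen, their neighbours FAM118B and TIRAP, a Toll-like receptor adaptor gene. Others are BLB1, BF1, BF2, BG8, BLEC2, TP53I3, VRK2, ABHD3 and NTHL1, the last of which lost its call in injected birds after rescaling and without LASI replicates 4 and 6.

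Comparing HASI with HASN asks how the HAS line responds to the antigen. Mitochondrially encoded genes were higher in injected HAS birds and OCLN, which encodes the tight junction protein occludin, was lower. ATP8 was at 5577 ± 1516 TPM in HASI and 1808 ± 573 in HASN (SD, n = 6), a log2 fold change of 1.64 (SE 0.26, adjusted p = 0.0011). ND4L was at 4274 ± 955 TPM against 1647 ± 289, a log2 fold change of 1.37 (SE 0.23, adjusted p = 0.002). OCLN (ENSGALG00000037316, chromosome 28, 3463016 to 3469363) was at 79.5 ± 20.1 TPM against 147 ± 26.2, a log2 fold change of -0.90 (SE 0.17, adjusted p = 0.00518), with all 6 injected birds below every uninjected one. The OCLN call ended after rescaling, with a log2 fold change of -0.62, and with only these groups fitted.

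Of the 13 mitochondrially encoded genes, 7 were higher and 0 lower (12 and 0 adjusted over the list alone), against 2 higher after rescaling and 12 with the span slope as a covariate. Their median log2 fold change rose from 0.79 (median SE 0.21) to 1.08 (0.35) on rescaling, so those calls ended because the error grew. The share of TPM these genes took split the HASN libraries, with 19.7%, 20.7% and 23.4% in replicates 3, 1 and 2 and 15.8% or less in replicates 4 to 6, against 21.4% to 38.0% in HASI. ND4L did not follow that split, at 2139 TPM or less in every HASN library and 3408 or more in every HASI library. Camera called the list higher (adjusted p = 3.6e-35) and the call held with an estimated correlation (adjusted p = 0.0114). The gene models of ATP8 and ND4L overlap those of ATP6 and ND4, so their reads are not fully separable. Other genes lower in HASI were ABI3, an actin regulator gene (log2 fold change -1.66, adjusted p = 0.000733), WIPF2, whose product acts in actin assembly (-1.36, adjusted p = 3.09e-05), CITED2 (-1.33) and THAP7 (-1.30, adjusted p = 3.69e-06). WIPF2 (ENSGALG00000037633, chromosome 27, 7205604 to 7209687) was at 7.08 ± 2.05 TPM against 19.3 ± 1.39. ENSGALG00000054033 on chromosome 5, without a symbol, was at 0.139 ± 0.124 TPM against 7.11 ± 4.12 (log2 fold change -2.69, adjusted p = 3.62e-07). Higher were HMBOX1 (1.30), the translation initiation gene EIF5B (1.02, adjusted p = 0.0132) and ATRX, a chromatin remodeller gene (1.21, adjusted p = 0.0143), the last of which did not pass without HASI replicate 3 (adjusted p = 0.051, the upper end of a range from 0.00337 over its alternatives). The calls of CITED2 and HMBOX1 ended with only the groups compared. Of the MHC genes, BF1 (log2 fold change -0.26), BF2 (-0.15) and BLB2 (-0.18) did not pass and changed sign after rescaling, and JCHAIN (0.02) and PIGR (-0.44) did not pass either. BLB1 was called lower (log2 fold change -0.69, adjusted p = 0.0274), but neither after rescaling, nor with only these groups fitted, nor without HASI replicate 1 (adjusted p = 0.0791), 3 (0.0967) or 4 (0.0679) or HASN replicate 2 (0.0526), 5 (0.0601) or 6 (0.0577), in a range of 0.00331 to 0.467 over its alternatives.

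The naming rule took 27 called genes in this comparison, of which 9 kept their call in every refit that used no fold threshold, ENSGALG00000049622 (log2 fold change 1.56) and ENSGALG00000031260 (1.88) among them. Of the 18 that lost it, those not yet given were ZBTB16 (-1.50), LPP (-1.42), ZFP36L2 (-1.39), KLF15 (-1.37), ASCL2 (-0.90), the neurofilament gene NEFL (-0.79), the cathepsin gene CTSS (-0.65), the endothelial gene ENG (-0.64), ATF6 of the unfolded protein response (-0.50), ENSGALG00000041565 (-1.85), MPHOSPH8 (1.13), POU2F1 (1.20) and the mitochondrially encoded ND6 (1.29). With only these groups fitted all of these 13 but ASCL2 lost it, and after rescaling KLF15, ASCL2, CTSS, ENG, ATF6 and ND6 did. Single libraries also ended it: HASI replicate 3 for ZBTB16 (adjusted p = 0.0502, range over its alternatives 0.00328 to 0.103), HASI replicate 1 for ASCL2 (0.0598, range 0.00496 to 0.065) and for NEFL (0.0548, range 0.00296 to 0.101), and HASI replicate 1 or 3 or HASN replicate 6 for ATF6 (up to 0.0584, range 0.0032 to 0.499). MPHOSPH8 lost it without HASI replicate 1, 3 or 5 or HASN replicate 1, 2 or 3 (up to 0.105, range 0.00489 to 0.144), and ND6 without HASI replicate 1 or 3 or HASN replicate 4, 5 or 6 (up to 0.112, range 7.53e-05 to 0.139). POU2F1 lost it without HASI replicate 1 (0.0677) or 3 (0.0542), in a range of 0.00291 to 0.073. ENSGALG00000041565 lost it without HASI replicate 1, 3 or 5 or HASN replicate 4, 5 or 6 (up to 0.121, range 7.03e-05 to 0.185). ZFP36L2 lost it without HASI replicate 1, 3, 4 or 5 or HASN replicate 4, 5 or 6 (up to 0.139, range 8.43e-06 to 0.219). LPP lost it without any HASI library or HASN replicate 4, 5 or 6 (up to 0.139, range 0.00298 to 0.193), and KLF15 without any HASI library or HASN replicate 4 or 6 (up to 0.123, range 0.0136 to 0.239). Both also lost it with no filter, and KLF15 with the W level as a covariate. CTSS lost it without HASI replicate 1, 3, 4 or 6 or HASN replicate 1, 4, 5 or 6 (up to 0.122, range 0.00842 to 0.271). ENG lost it without HASI replicates 1 to 4 or HASN replicate 2, 4, 5 or 6 (up to 0.137, range 0.0119 to 0.288).

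Genes on the small chromosomes 25 and 30 to 33, 720 of those tested and grouped after the values were seen, made up 73 of the 265 called (odds ratio 7.27, 95% interval 5.41 to 9.68, Fisher's exact test, adjusted p = 2.78e-31). The 265 called genes were 32 higher and 233 lower, and after rescaling 145 were called, 67 higher and 78 lower. The count was 115 without HASI replicate 1, 108 without HASI replicate 3, 176 without HASN replicate 4 and 161 without HASN replicate 6. It was 57 when only these groups were fitted, 1496 with the span slope as a covariate and 1595 with 2 surrogate variables. Whether the uneven span slopes within HASN lowered the count to 57 was not tested here either.

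**Figure D3:**
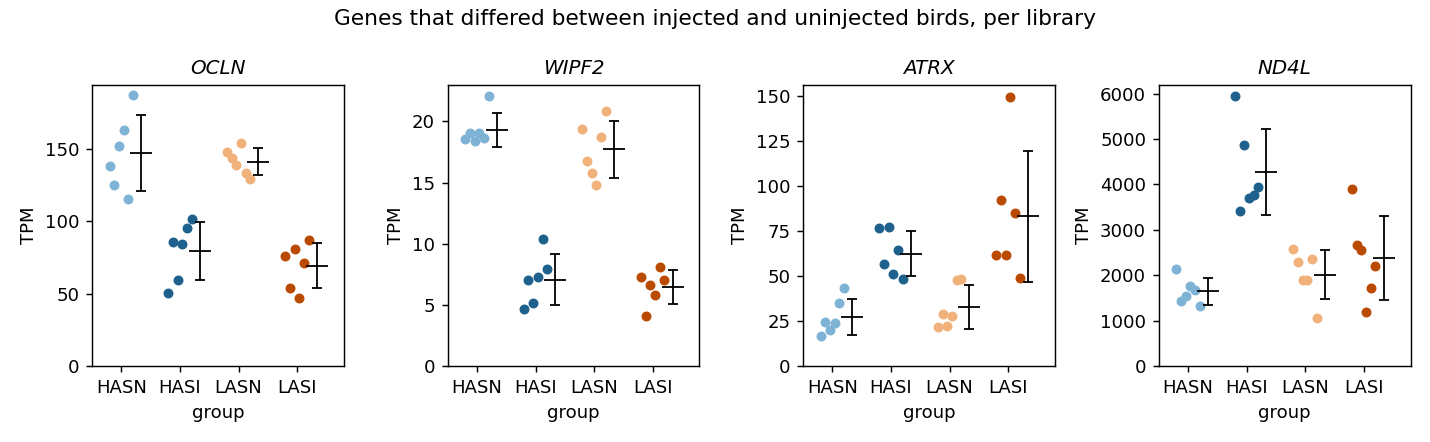
TPM per library (points) of OCLN, WIPF2, ATRX and ND4L in the 4 groups, with the mean and SD of 6 libraries in black. OCLN averaged 147 in HASN, 79.5 in HASI, 141 in LASN and 69.4 in LASI, and its call in HAS birds ended after rescaling.

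Comparing LASI with LASN asks how the LAS line responds. Of all tested genes 28.9% were called lower in injected LAS birds and 2.18% higher, with OCLN and FOSL2 among the lower and ATRX among the higher. OCLN was at 69.4 ± 15.6 TPM in LASI and 141 ± 9.2 in LASN (SD, n = 6), a log2 fold change of -1.04 (SE 0.17, adjusted p = 0.00108). FOSL2, a transcription factor gene of the immediate early list, was at 14.1 ± 13.2 TPM against 88.7 ± 32.8 (log2 fold change -2.81, SE 0.57, adjusted p = 0.00634, and -1.42 with the span slope as a covariate). ATRX was at 83.2 ± 36.3 TPM against 32.8 ± 12.1 (log2 fold change 1.29, SE 0.26, adjusted p = 0.00622). These LASI libraries are also those with the steeper span slope, -0.18 against -0.05.

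Of 45 genes of enterocyte nutrient absorption, 0 were higher and 15 lower (0 and 22 adjusted over the list alone), 1 and 8 after rescaling and 0 and 1 with the span slope as a covariate. MYO7B, a brush border myosin gene, kept its call in both and was at 10.7 ± 15.4 TPM in LASI against 67.8 ± 40.1 (log2 fold change -3.06, adjusted p = 0.0158), but its log2 fold change was -0.96 with the slope. The 25 genes of crypt stem cells and Wnt targets had 1 higher and 9 lower members (1 and 14 adjusted over the list alone), 3 and 6 after rescaling and 0 and 1 with the slope, among them ZNRF3 (log2 fold change -1.73, and -0.57 with the slope). Of 27 tight junction and adhesion genes 1 was higher and 8 were lower (1 and 10 adjusted over the list alone), 2 and 7 after rescaling and 0 and 1, OCLN, with the slope. Against 28.9% of all tested genes lower, camera called none of these 3 lists (adjusted p = 0.198, 0.329 and 0.609). Of 29 T cell and cytotoxic cell genes 1 was higher and 6 were lower (1 and 5 adjusted over the list alone), 1 and 5 after rescaling and 1 and 1 with the slope, with BCL11B, a transcription factor gene of T cells, at a log2 fold change of -2.16 (-0.96 with the slope). The 23 B cell and plasma cell genes had 0 higher and 4 lower members (0 and 3 adjusted over the list alone), 0 and 3 after rescaling and 0 and 2 with the slope, with the plasma cell regulator gene PRDM1 at -1.70 (-0.68 with the slope). The 33 immediate early and heat shock genes had 0 higher and 8 lower members, the same adjusted over the list alone, 3 and 6 after rescaling and 0 and 4 with the slope, with ZFP36L1 at -1.59 (-0.81 with the slope) beside FOSL2. Camera called none of the T cell, B cell and immediate early lists either (adjusted p = 0.524, 0.882 and 0.902), and each held a smaller share of lower members than the 28.9% of all tested genes. Of 39 cytokine and inflammation genes 3 were higher and 4 lower (2 and 4 adjusted over the list alone), 6 and 3 after rescaling and 1 and 0 with the slope. The chemokine gene CCL17 was at 13.1 ± 12.1 TPM against 3.84 ± 2.73 (log2 fold change 1.46, adjusted p = 0.0163), a mean that holds 1 library at 37.6 TPM. Camera called the cytokine list higher than other genes (adjusted p = 0.00138, and adjusted p = 0.654 with an estimated correlation).

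Of the 13 mitochondrially encoded genes 9 were higher and 0 lower (10 and 0 adjusted over the list alone), 10 and 0 after rescaling and 0 and 0 with the span slope as a covariate, where their median log2 fold change went from 0.60 (median SE 0.21) to 0.27 (0.18). Camera gave an adjusted p of 1.6e-12, which was lost (adjusted p = 0.291 with an estimated correlation). The 76 ribosomal protein genes had 27 higher and 6 lower members (35 and 7 adjusted over the list alone), 48 and 5 after rescaling and 1 and 1 with the slope, with RPL22L1 at a log2 fold change of 0.65. Camera gave an adjusted p of 1.6e-26 for them, also lost (adjusted p = 0.291 with an estimated correlation). Further genes lower in LASI were the zinc and manganese transporter gene SLC30A10 (log2 fold change -3.13, and -1.59 with the slope), ABHD2 (-3.11 and -1.05), the glycosyltransferase gene MGAT5 (-3.02 and -0.94), the triglyceride lipase gene PNPLA2 (-2.93 and -0.997) and HELZ2 (-2.34 and -0.91). Higher were OST4 (2.70), a subunit gene of the oligosaccharyltransferase, POU2F1 (1.32) and PNRC1 (1.31, adjusted p = 0.000828). The class I and II genes BF1 (log2 fold change -0.24), BF2 (-0.08), BLB1 (0.10) and BLB2 (0.36) did not pass, with BF1 and BF2 above 0 after rescaling, nor did JCHAIN (-0.71, adjusted p = 0.0668) and PIGR (-0.17).

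The naming rule took 59 called genes here, of which 19 kept their call in every refit that used no fold threshold, ENSGALG00000020869 (log2 fold change -2.83) among them. The median absolute log2 fold change of these 19 was 2.16, and 0.997 with the span slope as a covariate. Of the 40 that lost it, 38 did so with the span slope as a covariate, all but SREBF1 (-0.76, lost after rescaling at -0.34) and PDGFRA (-2.61). By fold change the rule had taken TMEM86A (-3.65), SOAT1 (-3.12), SLC22A5 (-2.96), ENSGALG00000049421 (-2.88), IL8L1 (1.52), TPM4 (2.28), HIST1H2B7 (2.51), ENSGALG00000046720 (3.60) and ENSGALG00000050199 (5.43). From the lists it had taken SEL1L (-2.48), TXNRD1 (-2.25), ERO1B (-2.09), TRIM25 (-1.91), TPH1 (-1.87), PDGFRB (-1.86), PARD6B (-1.85), ACACA (-1.64), PTPRN2 (-1.53), SLC27A4 (-1.50), NLRC5 (-1.41), NLRC3 (-1.30), TRAT1 (-1.28), GFI1 (-1.26), FLT3 (-1.21), RET (-1.19), GFRA1 (-1.14), CCR9 (-1.13), FOXM1 (-1.11), MSI1 (-1.10), CENPE (-1.05), SPDEF (-0.95), IKZF3 (-0.94), NR1H4 (-0.79), NQO2 (-0.55), RAMP2 (0.54), RPS24 (0.58), ND3 (1.04) and ND6 (1.19). Rescaling also ended the calls of SPDEF, NR1H4 and NQO2. Without 1 library 23 lost their call. PDGFRA, SLC22A5, SEL1L, TXNRD1, ERO1B, PDGFRB, ACACA, PTPRN2, ENSGALG00000046720 and ENSGALG00000050199 lost it without LASI replicate 2, 4 or 5 or LASN replicate 5 or 6, with an adjusted p of up to 0.0674, and PDGFRA, the gene of them that kept its call with the slope, of up to 0.0535 (range over its alternatives 0.000944 to 0.0535). GFI1 lost it without these or LASN replicate 2 (up to 0.0882), and RET (up to 0.0714) and TPM4 (up to 0.0776) without these or LASN replicate 4. TMEM86A lost it without LASI replicate 2 or 4 (up to 0.0514), TRIM25 without LASI replicate 5 (0.0504), RAMP2 without LASI replicate 2 (0.0527) and SLC27A4 without LASI replicate 2 or 4 or LASN replicate 6 (up to 0.0564). FLT3 lost it without LASI replicate 4 or 5 or LASN replicate 5 or 6 (up to 0.0549), FOXM1 without LASI replicate 2 or 5 or LASN replicate 5 or 6 (up to 0.0582) and IKZF3 without LASI replicate 2 or 4 or LASN replicate 5 or 6 (up to 0.0632). IL8L1 lost it without LASI replicate 4 or 5 or LASN replicate 4 or 6 (up to 0.0663), HIST1H2B7 without LASI replicate 2, 3, 5 or 6 or any LASN library but replicate 5 (up to 0.103) and NQO2 without LASI replicate 1, 2, 4 or 5 or any LASN library but replicate 3 (up to 0.104). Over all alternatives of these 23 genes the adjusted p ranged from 0.000944 to 0.656.

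The log2 fold changes of LASI against LASN fell with the span of the gene (Pearson r = -0.345 with log2 span). They also did so in HASN vs LASN (-0.322) and HASI vs HASN (-0.218), but not in HASI vs LASI (0.071). The 1328 genes of shortest span, with a median of 1.68 kb, had a median log2 fold change of 0.02 and 70 higher and 207 lower calls. The 1328 genes of longest span, with a median of 119 kb, had a median of -0.65 and 17 higher and 601 lower calls. In all 4133 genes were called, 289 higher and 3844 lower, and 4171 after rescaling, 1593 higher and 2578 lower. The median log2 fold change of all genes was -0.33 before rescaling. With the span slope as a covariate 774 genes were called, 126 higher and 648 lower, and 633 of the 4133 were called in both, with a median absolute log2 fold change of 1.61 without the covariate and 0.71 with it. Adding 2 surrogate variables gave 1561. The count was 1392 without LASI replicate 2, 1438 without LASI replicate 4, 1416 without LASI replicate 5, 1490 without LASN replicate 5 and 1355 without LASN replicate 6.

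**Figure D4:**
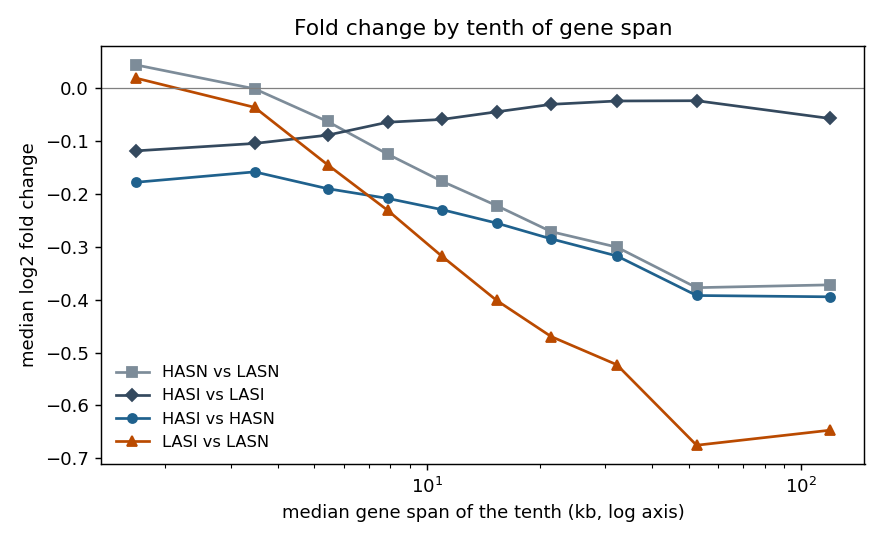
Median log2 fold change (vertical axis) of the tested genes, split by genomic span into 10 sets of nearly equal size and drawn at the median span of each set (kb, log axis), for the 4 comparisons. In LASI against LASN the median went from 0.02 in the shortest genes to -0.65 in the longest.

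Some genes were called between injected and uninjected birds in both lines. The libraries were separate, but the fit shared 1 estimate of each gene's spread. The median log2 fold change of all genes was also below 0 in both lines (-0.26 in HAS and -0.33 in LAS birds). The numbers expected by chance and the p-value therefore assume more independence than there is, and the overlap was not computed after rescaling. Of the 265 genes called in HAS birds and the 4133 called in LAS birds, 174 were shared with the same direction and 0 with opposite directions, 28 of them higher, where 0.696 would be shared by chance, and 146 lower, where 67.4 would be (Fisher's exact test for the overlap, p = 1.87e-31 across genes). The shared higher genes include ATRX, POU2F1, EIF5B, HMBOX1 and 4 mitochondrially encoded genes, and the shared lower genes include OCLN, WIPF2, ABI3, CITED2 and THAP7. POU2F1 did not pass in HAS birds without HASI replicate 1 (adjusted p = 0.0677, range over its alternatives 0.00291 to 0.073) or 3. In LAS birds the calls of CITED2 (adjusted p = 0.174) and of the 4 mitochondrially encoded genes, CYTB, ND2, ND4 and ND6 (0.157 to 0.434), ended with the span slope as a covariate. CYTB, ND2 and ND4 were chosen after their values were seen. With the span slope as a covariate 458 genes were shared.

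The average of the injected minus uninjected differences of both lines rested on all 24 libraries. It called 5461 genes, 310 higher and 5151 lower, or 1787 and 2640 after rescaling. A gene can be called in this average through a change in either line alone, so its calls need not be shared by the lines. ENSGALG00000054033 (log2 fold change -2.53, SE 0.16, adjusted p = 1.01e-09) and OCLN (-0.97, SE 0.12, adjusted p = 1.38e-05) were lower in injected birds, as was ASCL2, a regulator gene of intestinal stem cells (-0.80, adjusted p = 0.000636). All 13 mitochondrially encoded genes were higher, also after rescaling, and 11 with the span slope as a covariate (camera adjusted p = 4.45e-25, and adjusted p = 0.0529 with an estimated correlation). Of 27 tight junction and adhesion genes 0 were higher and 15 lower (0 and 18 adjusted over the list alone), against 2 and 4 after rescaling and 0 and 5 with the slope. Without either, 38.8% of all tested genes were lower and camera did not call the list (adjusted p = 0.52). Of 25 crypt stem cell and Wnt target genes 1 was higher and 15 were lower (1 and 16 adjusted over the list alone), against 2 and 11 after rescaling and 0 and 6 with the slope, and camera did not call this list without them either (adjusted p = 0.223).

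For this average the naming rule took 61 called genes, of which 34 kept their call in every refit that used no fold threshold, with a median absolute log2 fold change of 1.26, and 0.77 with the span slope as a covariate. By fold change these were, besides ENSGALG00000054033, the taurine transporter gene SLC6A6 (log2 fold change -2.35), FOSL2 (-2.19), MYO7B (-2.17), ENSGALG00000041565 (-2.16), MGAT5 (-2.12), ABHD2 (-2.11), HIPK1 (-2.05), ATP8 (1.12), HMBOX1 (1.13), NFIB (1.19), ND6 (1.24), ATRX (1.25), POU2F1 (1.26) and OST4 (2.12). From the lists they were PDGFRA (-1.89), HELZ2 (-1.76), SEL1L (-1.72), BCL11B (-1.61), ZFP36L1 (-1.43), TPH1 (-1.38), PRDM1 (-1.29), PARD6B (-1.26), ACACA (-1.20), NLRC3 (-1.06), NLRC5 (-1.04), LCK (-1.04), CENPE (-0.87), MSI1 (-0.84), NEFL (-0.64), CD40 (-0.59) and GHRL (0.52), besides OCLN and ASCL2. The span slope as a covariate ended the calls of 21, among them TMEM86A (-2.35), SOAT1 (-2.05), TXNRD1 (-1.56), TNFAIP3 (-1.24), GFRA1 (-0.80), GSTA3 (-0.80), FLT3 (-0.79), AGR3 (-0.77), FOXM1 (-0.77), CCR9 (-0.76), MYOCD (-0.67), CREB3L3 (-0.64), TIE1 (-0.53), SPDEF (-0.51), CTSS (-0.40), RPS24 (0.36), RPL22L1 (0.40), TPM4 (1.71), ENSGALG00000046720 (2.85) and ENSGALG00000050199 (3.48). Rescaling ended those of 12, which were AGR3, MYOCD, CREB3L3, TIE1, SPDEF and CTSS again, PGLYRP2 (-0.61), NR1H4 (-0.56), SREBF1 (-0.56), ENG (-0.46), ATF6 (-0.43) and BLB1 (-0.29, and 0.063 after rescaling). TIE1 also lost its call without HASI replicate 1 or HASN replicate 6 (adjusted p up to 0.0515, range over its alternatives 0.00679 to 0.333) and ENSGALG00000050199 without HASI replicate 1 or HASN replicate 4 or 6 (up to 0.0516, range 0.00477 to 0.454). BLB1 kept it without HASI replicate 2 or 5, HASN replicate 3 or 4, LASI replicate 5 or LASN replicate 2 or 4 and lost it without each of the other 17 libraries (up to 0.0902, range 0.0211 to 0.787).

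The count was 2295 with the span slope as a covariate and 2883 with 2 surrogate variables.

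The interaction asks whether the difference between injected and uninjected birds is the same in both lines. RFLNA had the smallest p (log2 difference 1.92, unadjusted p = 8.37e-05 from limma, adjusted p = 0.736), followed by KIRREL3 (1.55, unadjusted p = 0.000123 from limma, adjusted p = 0.736). KIRREL3 was at 73.7 TPM in LASN and 22.3 in LASI, and at 0.533 and 0.277 in the HAS groups, close to the floor. RFLNA was at 0.480 and 0.110 TPM in HASN and HASI and ENSGALG00000053834 at 0 and 0.00881, where log2(TPM + 1) leaves little or no room to fall, so a fall like that in LAS birds could not show there. ENSGALG00000053834 (log2 difference 0.83), CEBPD (-1.24) and TMEM158 (-1.17) followed, and BLB1 had a log2 difference of -0.79 (unadjusted p = 0.00248 from limma, adjusted p = 0.75). Camera called 10 of 24 lists, 3 higher and 7 lower, and 0 of them held with an estimated correlation, the MHC and antigen presentation list coming closest (adjusted p = 0.267 with an estimated correlation). limma called 0 genes at the adjusted threshold and 606 at an unadjusted p under 0.05, fewer than the 664 that chance would give, and no other tool was run. Without a filter it called 1, ENSGALG00000050358, which is listed at 0 TPM in every HASN bird and was chosen after its values were seen. Leaving out LASI replicate 6 gave 3 calls, RFLNA (2.16), KIRREL3 (1.74) and ENSGALG00000053834 (0.94). Leaving out LASN replicate 4 gave 2, ENSGALG00000053834 (0.95) and ENSGALG00000031497 (1.78, also chosen after its values were seen).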

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

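The tests of gene span, mitochondrial share, small chromosomes, related gene copies and chromosome 16 were chosen after the results were seen. The tests of single libraries and of other splits of the samples were planned. Splits fitted with the slope as a covariate are the exception and were added after the data were seen, as the slope was.

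In 500 tests of a gene or library measure within a group of 6, 24 had their highest or lowest library farther from the others than Dixon's test allows, where chance gives about 1 in 20. TPM of RFLNA was 2.40 in LASI replicate 6. TP53I3 was at 13.2 TPM in LASI replicate 4, below the rest of its group. BF1 was lowest in LASN replicate 2 at 2803. CCL4_1 was lowest in HASN replicate 6 at 12.4. ANKRD33 was highest in LASN replicate 6 at 4.63. CLDN1 was lowest in HASI replicate 1 at 1.15. HIST1H103 was highest in LASN replicate 1 at 11.9. ABI3 was lowest in LASI replicate 4 at 2.86. WIPF2 was highest in HASN replicate 6 at 22.1. ND4L was lowest in LASN replicate 6 at 1055. TPH1 was lowest in LASN replicate 3 at 2.45 and highest in LASI replicate 6 at 5.82. LASI replicate 6 was also highest in BCL11B at 17.3, in PRDM1 at 7.13 and in ACACA at 14.4. LASI replicate 4 was highest in CCL17 at 37.6 and in IL8L1 at 48.5. HIST1H2B7 was at 21.9 in HASN replicate 1 and at 6.76 in LASN replicate 5, with the other libraries of both groups listed at 0. Of genes without a symbol, ENSGALG00000050131 was lowest in LASN replicate 3 at 38.9, and ENSGALG00000033498 was highest in LASN replicate 6 at 0.269 and in LASI replicate 6 at 0.642. ENSGALG00000051027 was highest in LASI replicate 5 at 252, and ENSGALG00000050199 was listed at 0 in LASI replicate 6.

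The first pattern is the 4133 genes called in injected LAS birds, 93.0% of them lower. A larger mitochondrial share that lowers all other TPM does not account for the number, since 4171 genes were called after median-ratio rescaling and 2867 were called in both; its part in the direction stays open, since rescaling centres the fold changes and so balances the directions whatever the cause. The length trend of the libraries may account for most of the calls: with the slope as a covariate 774 were called, and in the 3500 genes whose call ended the median absolute log2 fold change went from 1.03 (median SE 0.33) to 0.30 (0.17), so the calls ended because the changes shrank and not because the error grew. The trend as the whole cause is argued against by 633 genes called in both fits, where no other split called more than 7 with the covariate, although simulated noise with the shared structure of the libraries gave 363 false calls in that fit in 1 of 5 draws and at most 20 in the other 4. A response to the antigen, or a difference in how RNA of the groups was handled, stays open, because slope and injection go together in the LAS line and no batch is in the labels.

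The second pattern is the share of genes on chromosomes 25 and 30 to 33 among the genes called in injected HAS birds. In HAS birds the odds ratio was 7.27 without the slope as a covariate and 4.60 (95% interval 3.88 to 5.44) with it. This does not decide on the length trend, since the mean slopes of HASI (-0.16) and HASN (-0.12) lay close together. Their difference did not pass (exact permutation p = 0.485), which does not show that it is absent. The log2 fold changes of this comparison also fell with gene span (Pearson r = -0.218). Lower calls numbered 37 in the 1328 genes of shortest span (median log2 fold change -0.18) and 4 in the 1328 of longest span (-0.39). The odds ratio was not computed with genes matched for span. Chance cannot be excluded for the 265 calls either, as 6 of 100 splits, the real one included, gave as many. In LAS birds the median log2 fold change of these genes minus that of large chromosomes was 0.19 without the covariate and -0.14 with it, so a lower level there appears in the adjusted fit alone, and a trend and its adjustment cannot be told apart from a response. Base composition of the transcripts may lie behind the HAS pattern, as the adjusted median followed chromosome length over 33 chromosomes (Spearman rho 0.818 in HAS and 0.836 in LAS birds), but no sequence was at hand, so it cannot be told apart from a response to the antigen.

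The third pattern is the line difference in the MHC on chromosome 16, where reads shared between related copies may explain the opposite differences at BF1 and BF2: their summed TPM differed by a log2 of 0.40 in uninjected birds (SDs 0.41 and 0.10, exact permutation p = 0.0541) and by 0.37 in injected birds (SDs 0.22 and 0.13, exact permutation p = 0.00216). For BLB1 and BLB2 the sum differed by 0.020 (SDs 0.37 and 0.19, exact permutation p = 0.907) and -0.46 (SDs 0.22 and 0.33, exact permutation p = 0.0108). The sums in injected birds differed beyond their spread, which goes against an exchange of reads as the whole cause there unless the copies differ in transcript length, which the table does not give. Sequence of one line that differs from the reference could lower mapping in HAS, where 84.6% of the 13 called genes were lower in either comparison. Of all called genes 71.8% in uninjected and 70.8% in injected birds were lower too. That share depended on the scaling, as 88 of 165 and 48 of 80 called genes were lower after median-ratio rescaling. The share on chromosome 16 was not computed after rescaling, so the direction does not decide on this explanation. Without reads these explanations cannot be told apart from regulation that differs between the lines, which remains untested.

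Other splits of the same samples were fitted for each comparison, 100 with the real one included, drawn of 462 where 2 groups were compared and by exchanging injection labels within each line for the interaction and for both lines together. For HASN vs LASN 4 of the 100 splits, the real one included, gave as many calls as the real 156. Without adjustment over the comparisons this makes chance unlikely and does not exclude it. The highest other split called 6429, which points to a structure of the samples other than the line. With the slope as a covariate the highest other split called 42, so this structure goes with the span slope. For HASI vs LASI the 100 splits make chance unlikely and do not exclude it (1 split, real 72, highest other 7). Simulated noise with the shared structure of the libraries gave 3114 false calls in 1 of 5 draws, though at most 2 in the other 4. All 72 calls were kept with the slope as a covariate, at a median absolute log2 fold change of 1.20 without it (median SE 0.19) and 1.21 with it (0.16). That refit could hardly have ended them. The slope was near equal in HASI (-0.16) and LASI (-0.18, exact permutation p = 0.747), and log2 fold changes hardly followed gene span (Pearson r = 0.071). The refit therefore decides nothing about the length trend. For HASI vs HASN chance cannot be excluded, as 6 splits gave 265 or more and the highest other gave 7715, again a structure of the samples. For LASI vs LASN (1 split, real 4133, highest other 3) and for both lines together (1 split, real 5461, highest other 1) chance is likewise made unlikely and not excluded. For the interaction the real count was 0, so all 100 splits had to give as many and the test decides nothing, and the highest other split called 5564, a structure of the samples. With the slope as a covariate chance is made unlikely and not excluded for HASN vs LASN (1 split, real 282, highest other 42) and LASI vs LASN (1 split, real 774, highest other 7). In that fit simulated noise gave 363 false calls for LASI vs LASN in 1 of 5 draws, and at most 20 in the other 4. Chance is less clearly made unlikely for HASI vs LASI (3 splits, real 288, highest other 1361, a structure of the samples). The same holds for HASI vs HASN (2 splits, real 1496, highest other 1554), since another split called more genes than the real one in either case.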

How the results depend on the processing

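The span slope as a covariate and the omission of LASI replicates 4 and 6 together were chosen after seeing the data; all other alternatives were planned, and those that need read counts were not run. Where a result moved, the cause was not tested unless stated. Counts stayed within 1.5 times under the filter at 1 TPM, the pseudocount of 0.1, the W level as a covariate and the replicate block (180 for HASN vs LASN, 83 for HASI vs LASI, 368 for HASI vs HASN, 5306 for LASI vs LASN, 0 for the interaction, 6398 for both lines). Median-ratio rescaling gave 145 for HASI vs HASN. No filter gave 1 for the interaction. With 2 surrogate variables the counts were 435 for HASN vs LASN, 406 for HASI vs LASI, 1595 for HASI vs HASN, 1561 for LASI vs LASN and 2883 for both lines. In the same order the slope as a covariate gave 282, 288, 1496, 774 and 2295, and a log2 fold change of at least 1, which by construction calls fewer, gave 87, 42, 58, 2295 and 1427. Fitting only the groups compared gave 67 for HASN vs LASN and 57 for HASI vs HASN, against 68 for HASI vs LASI and 5300 for LASI vs LASN. Without LASI replicates 4 and 6 HASI vs LASI gave 40. Over the omission of each library the counts ranged from 104 to 187 for HASN vs LASN, 45 to 68 for HASI vs LASI, 108 to 310 for HASI vs HASN, 1355 to 5977 for LASI vs LASN, 0 to 3 for the interaction and 3971 to 6839 for both lines. In the average of both lines BLB1 turned from -0.29 to 0.063 after rescaling and lost its call without 17 of the 24 libraries, each in turn. Of 197 calls of named genes, 60 were lost with the slope, 34 with the surrogate variables and 33 with rescaling, and of the 136 refitted with only the groups compared 29 were lost. A pseudocount of 0.1 moved genes near the floor, for instance RFLNA to -3.78 and PCSK4 to 2.44 in HASN vs LASN. Some named genes had wider ranges over all settings, such as ENSGALG00000054033 (-4.87 to -2.48 in HASI vs HASN) and ANKRD33 (-3.61 to -1.43 in HASI vs LASI). Of the 26 list calls in the comparisons of single groups, 24 were lost with an estimated correlation. Fry, which asks whether a list moves on balance and not whether it differs from other genes, did not pass 23 of these 26 lists. The unknown depth leaves the precision of low values open.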

Other observations

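The clustering test was planned before its result, after the pair ST3GAL4 and KIRREL3 had been noticed, and the other values here were chosen after they were seen.

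Injected LAS birds had 0 higher and 5 lower of 14 goblet cell and mucus genes (0 and 5 adjusted over the list alone), against 0 and 2 after rescaling and 0 and 0 with the slope as a covariate, and camera did not call the list (adjusted p = 0.336). Of 30 interferon-stimulated genes, 0 were higher and 5 lower (0 and 2 adjusted over the list alone), against 0 and 2 after rescaling and 0 and 1 with the slope. That is a smaller share than the 28.9% of all tested genes that were lower, and camera did not call the list (adjusted p = 0.13), whose median log2 fold change was -0.13 against -0.33 for all genes. In injected HAS birds 0 of 30 genes of cholesterol and fatty acid synthesis were called, while camera placed the list above other genes (adjusted p = 4.36e-06, and adjusted p = 0.766 with an estimated correlation). On chromosome 31, 10 of 110 tested genes were called between HASN and LASN, all 10 higher in HASN, and 2 between HASI and LASI, both higher in HASI. One of the genes with a symbol there, CHIR-B6, is a member of the chicken immunoglobulin-like receptor family. It had log2 fold changes of 1.13 in uninjected and 0.74 in injected birds, and was not called in both comparisons.

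Genes that differ between the lines may lie together on the chromosomes, as linked regions fixed by selection would. Outside chromosome 16, the 170 genes called in either line comparison formed 48 pairs within 250 kb, against a median of 20 (upper end of their central range 30) in 10000 random sets. Every pair within that distance was counted, so a run of close genes gave several pairs. The pair ST3GAL4 and KIRREL3 that had been noticed before was counted too. The share of random sets with as many was 1e-04, the smallest they can give. FAM118B, TIRAP, ST3GAL4 and KIRREL3 on chromosome 24 and DDB2 with PACSIN3 on chromosome 5 form such pairs. Overlapping gene models that share reads, and related genes side by side such as histone genes on chromosome 1, would also give pairs. Neither was set apart.

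The span slope was -0.22, -0.28 and -0.24 in HASN replicates 1 to 3 and 0.0041, -0.02 and 0.01 in HASN replicates 4 to 6. The level of chromosome W genes, scored over 30 genes, was high in 3 HASN, 4 HASI, 3 LASN and 3 LASI libraries and low in the others.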
